A study of Mus musculus with 2 samples.

How the data were processed

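Nucleoplasmic RNA of mouse bone-marrow-derived macrophages was sequenced after depletion of ribosomal RNA, with a size range of 250 to 400 per the labels. The authors deposited 3 tables per library, each made from that library alone. The deposited gene and transcript tables of the first quantification give expected counts, TPM, posterior-mean TPM and FPKM, and their column names are those that RSEM writes, per the file headers. The deposited table of the second quantification gives estimated counts and TPM per transcript, with column names that kallisto writes, per the file headers. The accompanying notes name the mm10 assembly and GENCODE release M21. The programs' versions, the aligner settings and the filters are not given in the sources used here. Deposited TPM is scaled over all entries of a table, and FPKM over fragments and effective length.

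All 55536 mouse gene identifiers were matched to the GENCODE M21 annotation, which gave symbols, coordinates, gene classes and transcript classes. The gene tables also held 96 spike-in entries with 0 counts in both libraries, 26248 numbered entries and a phiX174 entry, which took 0.823% of counts in replicate 1 and 0.206% in replicate 2. These stayed out of library sizes and comparisons. Totals over genes were 18194818 and 18667509, so 3 counts, the limit that a count of 0 allows, correspond to 0.165 and 0.161 CPM (counts scaled to library size). Shares of counts have exact Clopper-Pearson 95% intervals. Reads without molecular identifiers are not independent molecules, so intervals and limits cover counting error only.

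Before the data were examined, 26 gene lists, the measures, the alternatives and the rule for named genes were fixed. The rule named all members of the immediate-early, NF-kB and early cytokine lists, the 3 highest and the lowest of each other list, the 10 highest nuclear-encoded protein-coding and long noncoding genes, and the 10 largest ratios in each direction among genes of length 300 or more with a mean scaled count of 50 or more. Rmrp and Ddit3 matched more than 1 identifier, and Rn45s and Rn18s matched none, so these 4 were not measured. The unit was as assumed. Values are means and SD over 2 libraries, and no test between groups was possible with 1 group.

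Expected counts were rounded to whole numbers and scaled by edgeR 4.0.16 (TMM) in R 4.3.3. Log2 ratios of replicate 2 over replicate 1 used a prior count of 0.5, with exact binomial 95% intervals. List medians were set against 10000 random lists drawn from 20 expression bins. Such lists ignore that co-regulated genes move together, so a percentile describes these 2 libraries only. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The ratio step was tested on simulated data: among 15556 genes, 50 of 50 genes raised by log2 2.5 and 44 of 50 lowered by log2 1.5 were called, as were 72 of 15356 unchanged genes. Among 100 simulated lists of 12 unchanged genes, 4 fell outside the central 95%. The simulated counts held counting error only, with genes independent of each other. In the real libraries the median absolute log2 ratio was 0.305, against 0.083 from counting alone, so these rates are not error rates for them.

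The alternatives included DESeq2 1.42.0 size factors, library totals, TPM ratios, other count and TPM minimums, other pseudocounts, FPKM, posterior-mean TPM, the second quantification and leaving out each replicate. Ratios adjusted for GC content or length (lowess with a span of 0.3), list medians from TPM ratios or the second quantification, and counts without mitochondrial genes and pseudogenes were added after seeing the data. The tests in the closing section were also defined after the ratios were seen. For mitochondrial RNAs, members with a nuclear copy were defined in 2 ways, by shared 31-base words with annotated pseudogenes and by position inside the copied span, and both outcomes are given. These replaced a first list of copied genes written from memory, which the shared words contradicted, and the change altered the outcome of 2 tests. The 6 nuclear copies were picked after their values were seen. The test of cytoplasmic RNA was first set against the lowest mitochondrial mRNA without an annotated copy, where the outcome turned on mt-Nd3 alone, and was then restated on list medians. The test of nucleolar yield was first run on snoRNAs, which only restated the pattern, and was replaced by a test on Cajal-body RNAs defined after some of their values were seen. The change left the explanation open where the first test had supported it. Quantification by estimated counts can split reads between copies and overlapping genes, and the strand setting is not given in the sources used here.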

Results

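RNA was measured in the nucleoplasm, the soluble part of the nucleus, of mouse bone-marrow-derived macrophages of the C57BL/6J strain. The cells had been exposed for 20 min to 100 ng/ml lipid A, the membrane-anchored part of bacterial lipopolysaccharide that is sensed by the receptor TLR4. Total RNA was depleted of ribosomal RNA and sequenced from 2 biological replicates of this 1 group. Both carry the same donor identifier in the labels, which number the replicates and do not say whether they are separate cultures or animals, so n = 2 counts libraries. Replicate 1 was made from 1 µg of RNA and replicate 2 from 500 ng, so RNA input and replicate cannot be told apart. The gene tables held 18194818 estimated counts in replicate 1 and 18667509 in replicate 2. No unstimulated library and no other cell fraction was analysed here, so levels and their spread are given and no change caused by lipid A was tested. Intervals cover counting error only.

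The first question was which genes of the response to TLR4 were present in nucleoplasmic RNA at this time. Immediate-early transcription factors and fast feedback regulators were abundant, and 20 of 20 listed members reached 1 TPM, a length-normalised unit of transcript abundance, in both libraries. The median TPM of that list was 158 ± 64.5 (SD, n = 2). On this TPM scale the median log2 ratio of replicate 2 over replicate 1 was -0.36 over 15557 genes. TPM differences between the replicates therefore include a shift that is not particular to the listed genes. Zfp36, whose protein destabilises cytokine mRNAs, stood at 447 ± 63.1 TPM (SD, n = 2) and ranked 37 among 22015 nuclear-encoded protein-coding genes. Fos, a subunit of the AP-1 factor, was at 281 TPM in replicate 1 and 405 TPM in replicate 2. Egr1, a zinc-finger transcription factor on chromosome 18 (34859823 to 34864984, mm10), was at 278 TPM in replicate 1 and 145 TPM in replicate 2. The second quantification put Egr1 at 98.5 and 104 TPM, and Fos at 131 and 339 TPM. Myc was the least abundant member, at 4.33 and 3.85 TPM.

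Genes for NF-kB subunits and their inhibitors were also present, with 12 of 12 members at 1 TPM or more in both libraries and a median TPM of 30.2 ± 15.3 (SD, n = 2). Nfkbia, which encodes the inhibitor IkB-alpha, lies on chromosome 12 (55489410 to 55492647, mm10) and stood at 616 TPM in replicate 1 and 191 TPM in replicate 2. Tnfaip3, which encodes the inhibitory enzyme A20, was at 298 ± 147 TPM (SD, n = 2). Of 20 early cytokine, chemokine and other rapidly induced genes, 18 reached 1 TPM in both libraries, and the median TPM was 128 ± 92.1 (SD, n = 2). Tnfaip2 was the most abundant, at 990 TPM in replicate 1 and 323 TPM in replicate 2. Tnf, on chromosome 17 (35199381 to 35202007, mm10), was at 404 ± 277 TPM (SD, n = 2), and the chemokine gene Cxcl2 was at 534 and 305 TPM. In the second quantification Cxcl2 was at 178 and 199 TPM, Tnf at 239 and 155 TPM, and Nfkbia at 363 and 257 TPM. Cxcl3 and Il23a were below 1 TPM in both libraries, although the second quantification put Il23a at 1.49 and 3.17 TPM.

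Genes that are usually induced later were scarce. Of 20 late-response members, 5 reached 1 TPM in both libraries and 14 were below it in both, and the median TPM was 0.61 ± 0.141 (SD, n = 2). The most abundant of them were Saa3, at 30.2 and 1.99 TPM, Ebi3, at 18.7 and 11.4 TPM, and Acod1, which makes itaconate, at 16.6 and 3.65 TPM. The second quantification put Saa3 at 14.3 and 4.29 TPM. Il12a, a subunit of interleukin 12, had 0 counts in replicate 1 and 1 count in replicate 2. Interferon-response genes lay between these groups, with 18 of 20 members at 1 TPM or more and a median TPM of 28.4 ± 16.1 (SD, n = 2). Rsad2, an antiviral gene, was at 121 and 67.6 TPM, whereas Cxcl9 had 8 counts and 0 counts, or 63.6 and 72.3 in the second quantification. On the log2(TPM + 0.1) scale, the median of the 40 early genes exceeded that of the 40 late and interferon genes by 4.26 ± 0.175 (SD, n = 2). The difference was 7.51 ± 0.556 against the late genes alone and 2.30 ± 0.0350 against the interferon genes alone (SD, n = 2). No p-value was computed across genes, because genes are not replicates.

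**Figure D1:**
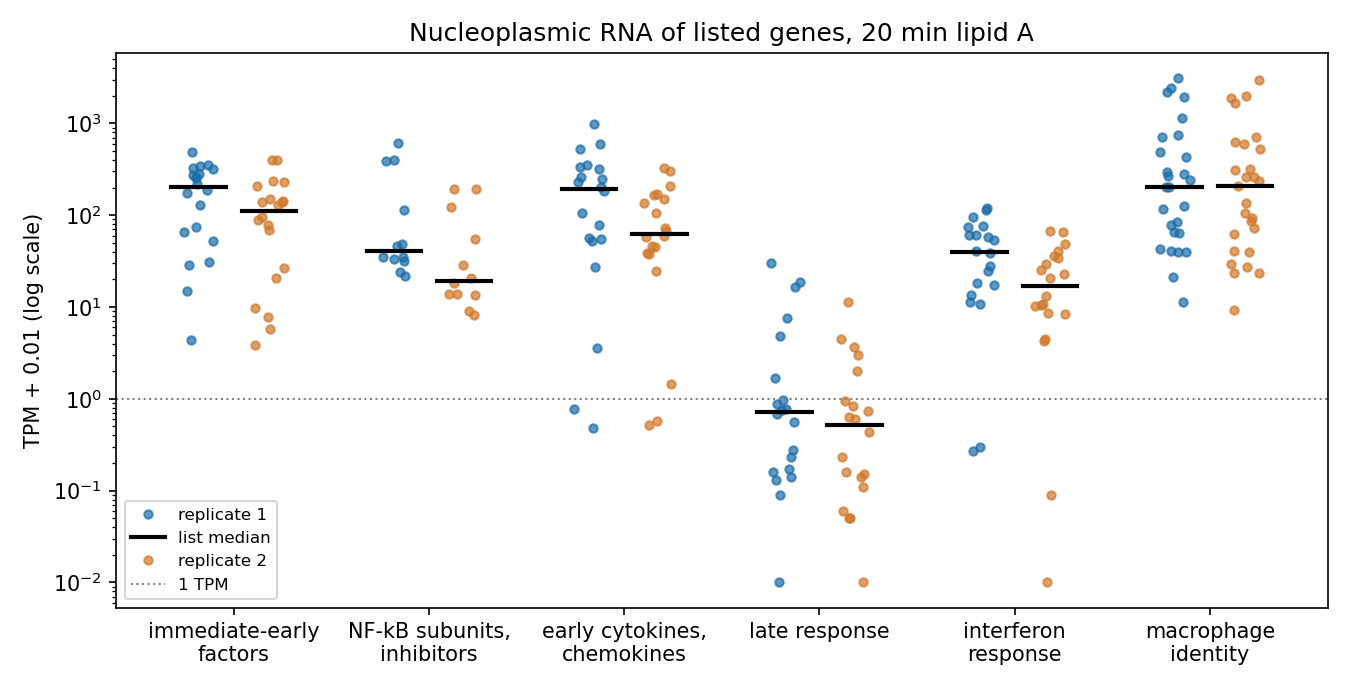
Points are the TPM of each listed gene in each replicate, plotted as TPM + 0.01 on a log axis, and black bars are list medians. Immediate-early, NF-kB and early cytokine genes lie mostly above 10 TPM in both replicates, and 14 of 20 late-response genes lie below 1 TPM in both.

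The libraries had the profile of macrophages, and the lists of markers of other marrow cells had low medians. All 27 macrophage identity genes reached 1 TPM in both libraries, with a median TPM of 207 ± 2.81 (SD, n = 2). Gpnmb was at 3027 ± 122 TPM, the lysosomal protease gene Ctsb at 2142 ± 376 TPM, and the lysozyme gene Lyz2 at 2109 ± 156 TPM (SD, n = 2). The lowest member, Cebpa, was at 10.4 TPM. Genes of lipid A sensing and TLR4 signalling were present for 23 of 24 members, led by the co-receptor gene Cd14 at 336 ± 39.9 TPM (SD, n = 2), and the lipopolysaccharide-binding protein gene Lbp was at 0.435 TPM. Median TPM was 0.108 for neutrophil, 0.125 for B cell, 0.395 for dendritic cell and 0.0175 for stromal markers, and 0 for T and NK cell and for erythroid markers. The mast cell and basophil markers had a median TPM of 0.025. Single markers at 1 TPM or more in both libraries were Pf4, a platelet chemokine gene, at 65.7 ± 4.95 TPM (SD, n = 2), and Alas2, Ighm, Kit, Zbtb46 and Itga2b, with means of 1.16 to 3.585 TPM. The median of the megakaryocyte list was 1.02 TPM. Stress genes had a median of 26.3 TPM and were led by the chaperone gene Hspa5 at 241 ± 110 TPM (SD, n = 2). Proliferation genes had a median of 1.35 TPM and replication-dependent histone genes 1.82 TPM. The most abundant nuclear-encoded protein-coding gene was Psap, which encodes the precursor of the saposins, at 4229 ± 1003 TPM (SD, n = 2).

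The second question was which classes of RNA the fraction held. Protein-coding genes, mitochondrial ones included, took 76.1% ± 0.383 of the counts (SD, n = 2). Long intergenic noncoding RNAs took 15.1% in replicate 1 and 13.0% in replicate 2. This class includes 2 loci that collect ribosomal RNA reads, Gm26917 (266762 and 31301 counts) and Gm42418 (55928 and 15175 counts). Malat1, a nuclear noncoding RNA on chromosome 19 (5795690 to 5802672, mm10), alone took 9.72% (exact 95% interval 9.71 to 9.74) and 10.2% (10.15 to 10.18). Neat1, the RNA scaffold of paraspeckles, took 2.12% and 1.22%, and Xist, the RNA that coats the inactive X chromosome, took 0.694% and 0.733%. Rn7sk, the 7SK RNA that holds the elongation factor P-TEFb, took 1.68% and 2.90% of the counts. Because TPM divides by length, the protein-coding share of TPM was 32.7% and 35.1%, and Rn7sk reached 126111 and 170383 TPM. The levels above therefore depend on the other classes in the total, and with TPM rescaled over long nuclear genes, without short RNAs, mitochondrial genes and ribosomal RNA loci, the immediate-early median was 476 TPM.

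Mitochondrially encoded RNAs and ribosomal RNA loci took different shares in the replicates. The 15 mitochondrial members took 3.19% (exact 95% interval 3.18 to 3.20) of counts in replicate 1 and 10.5% (10.52 to 10.54) in replicate 2. Among them mt-Nd2, which shared 0% of its 31-base words with annotated nuclear copies, had 17690 and 105424 counts. Neither library was therefore free of RNA from outside the nucleus. Loci that collect ribosomal RNA reads took 1.88% and 0.253%. Gm26917, the most abundant of them, had 266762 counts in replicate 1 and 31301 in replicate 2. Unprocessed pseudogenes took 0.781% and 2.86%, but most of this lay on 5 mitochondrial-like pseudogenes, which took 0.725% and 2.76%. Ribosomal protein genes took 0.0629% and 0.0602%.

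**Figure D2:**
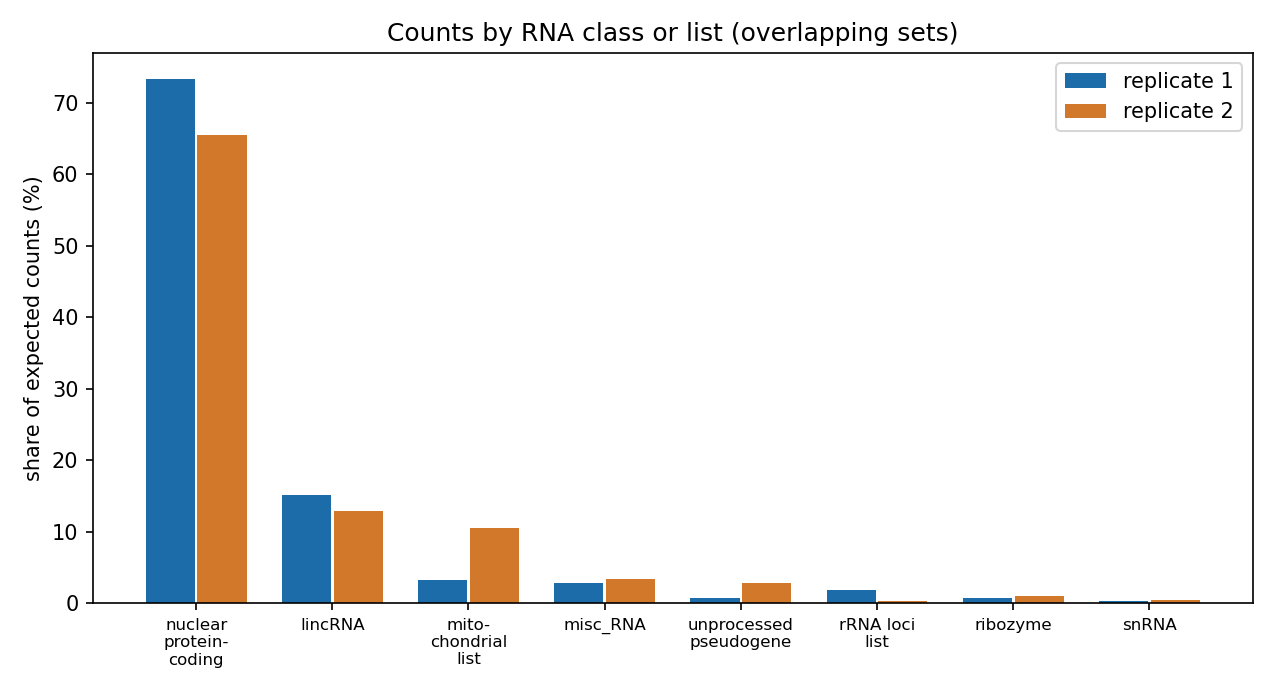
Bars give the share of estimated counts in percent for each RNA class or list, 1 bar per replicate and starting at 0. The mitochondrial list is at 3.19% in replicate 1 and 10.5% in replicate 2, and nuclear-encoded protein-coding genes are at 73.3% and 65.5%.

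Nuclear RNA holds incompletely spliced transcripts, so the share of each gene's TPM on transcripts annotated as retaining an intron was examined. In genes known for detained introns that share had a median of 46.4% ± 5.64 (SD, n = 2), at percentile 82.7 of 10000 random lists matched on expression. Over all 6420 genes with such a transcript and a mean of 1 TPM or more the median was 32.2% ± 0.615 (SD, n = 2). As a share of all counts, such transcripts took only 12.8% in replicate 1 and 11.4% in replicate 2. TPM divides by length, so shares of TPM give short transcripts more weight. List medians rest only on members that meet these conditions and do not describe the rest of a list. They covered 17 of 18 detained-intron, 6 of 20 immediate-early, 9 of 12 NF-kB and 9 of 20 early cytokine genes. They also covered 9 of 20 interferon-response, 11 of 27 macrophage identity, 15 of 18 ribosomal protein and 8 of 10 housekeeping genes. The share was 72.7% ± 2.14 in Ccnl1, a cyclin gene, 65.4% ± 3.29 in Rsrp1 and 5.51% ± 0.503 in the helicase gene Ddx5 (SD, n = 2). Among early genes it was 84.8% ± 5.90 in Dusp1 and 6.11% ± 0.535 in Nfkbia (SD, n = 2), although the second quantification gave 28.0% for Nfkbia. Early cytokine genes had a median of 51.6% ± 5.41 (percentile 90.3, and 99.3 for shares of counts) and immediate-early genes 44.8% ± 7.21 (percentile 76.1, and 79.7 for shares of counts). NF-kB genes had 45.2% ± 1.24 (percentile 84.4), but percentile 45.4 for shares of counts (20.9%) and 14.8 with the second quantification (28.0%). Interferon-response genes had 22.9% in replicate 1 and 55.4% in replicate 2. Medians were low in ribosomal protein genes, at 22.2% ± 2.31 (percentile 2.31), housekeeping genes, at 18.1% ± 0.113 (percentile 2.42), and macrophage identity genes, at 23.0% ± 4.10 (percentile 3.36; SD, n = 2), which were at percentile 10.45 without replicate 1 and at 9.07 for shares of counts, with a share of 10.5%. The position of the detained-intron list depended on the measure, with percentile 99.97 for shares of counts and 97.8 without replicate 1.

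The replicates were then compared gene by gene, a comparison of 2 libraries and not of conditions. Inhibitors and subunits of NF-kB were lower in replicate 2 in 12 of 12 members, with a median log2 ratio of -1.04 and a percentile of 0 among 10000 random lists matched on expression. Nfkbia had a log2 ratio of -1.34 (exact 95% counting interval -1.38 to -1.29), and Relb had -1.20. The ratio also fell with transcript GC content, and with that trend taken out the NF-kB median was -0.78. Early cytokine genes were lower in 17 of 20 members, 15 of them beyond counting error (median -0.67, percentile 0). Icam1, an adhesion molecule gene, had -1.73 and Tnf had -1.17, whereas Ptgs2, the gene for cyclooxygenase 2, had 0.83. Immediate-early genes were lower in 16 of 20 members (median -0.42, percentile 0), with Egr3 at -2.07 and Egr2 at -1.66, but Fosb at 1.27 and Fos at 0.67. Interferon-response genes were lower in 16 of 18 members with enough counts (median -0.65, percentile 0), and late-response genes in 10 of 11 (median -0.99, percentile 0). Many late-response members had few counts, with 8 lower and 1 higher beyond counting error among all 20. The late-response median was -0.77 with the second quantification, and its percentile was 2.24 with TPM ratios. Genes of TLR4 sensing had a median of -0.09 (percentile 24.4) and macrophage identity genes 0.13 (percentile 98.9). The macrophage median was 0.0106 with the GC trend taken out (percentile 92.1, inside the central 95%), 0.0302 with library totals and -0.22 with TPM ratios, a scale on which the median of all genes lay at -0.36.

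Of 15557 genes with a mean scaled count of 10 or more, 678 were over 2-fold higher in replicate 2 and 570 were over 2-fold higher in replicate 1, with counting intervals clear of 0. That split was 529 and 746 with library totals, 319 and 1707 with TPM ratios, 146 and 194 among genes with a mean scaled count of 100 or more, and 1852 and 1043 with the second quantification. A planned check for copies of 1 library gave a chi-square of 131 per degree of freedom, so the 2 were not copies, and it does not measure biological spread. Across genes, which are not independent replicates, Pearson's r of log2(TPM + 0.1) was 0.956 and Spearman's rho was 0.963. The mitochondrial gene mt-Atp6 had a log2 ratio of 3.29 and mt-Nd2 had 2.63. Of its 31-base words, mt-Atp6 shared 99.5% with annotated nuclear copies. CT010467.1, a ribosomal RNA locus, had -4.50, with 19728 and 839 counts, but 98201 and 20489 in the second quantification. Several of the largest ratios belong to genes that overlap or copy others and are uncertain. Gm37376 had 1586 counts in replicate 1 and 0 in replicate 2, lies on the opposite strand within Malat1, and had 29128 and 34649 counts in the second quantification. Slc15a2, a peptide transporter gene, had 120 and 12 counts, but 205 and 52 in the second quantification.

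**Figure D3:**
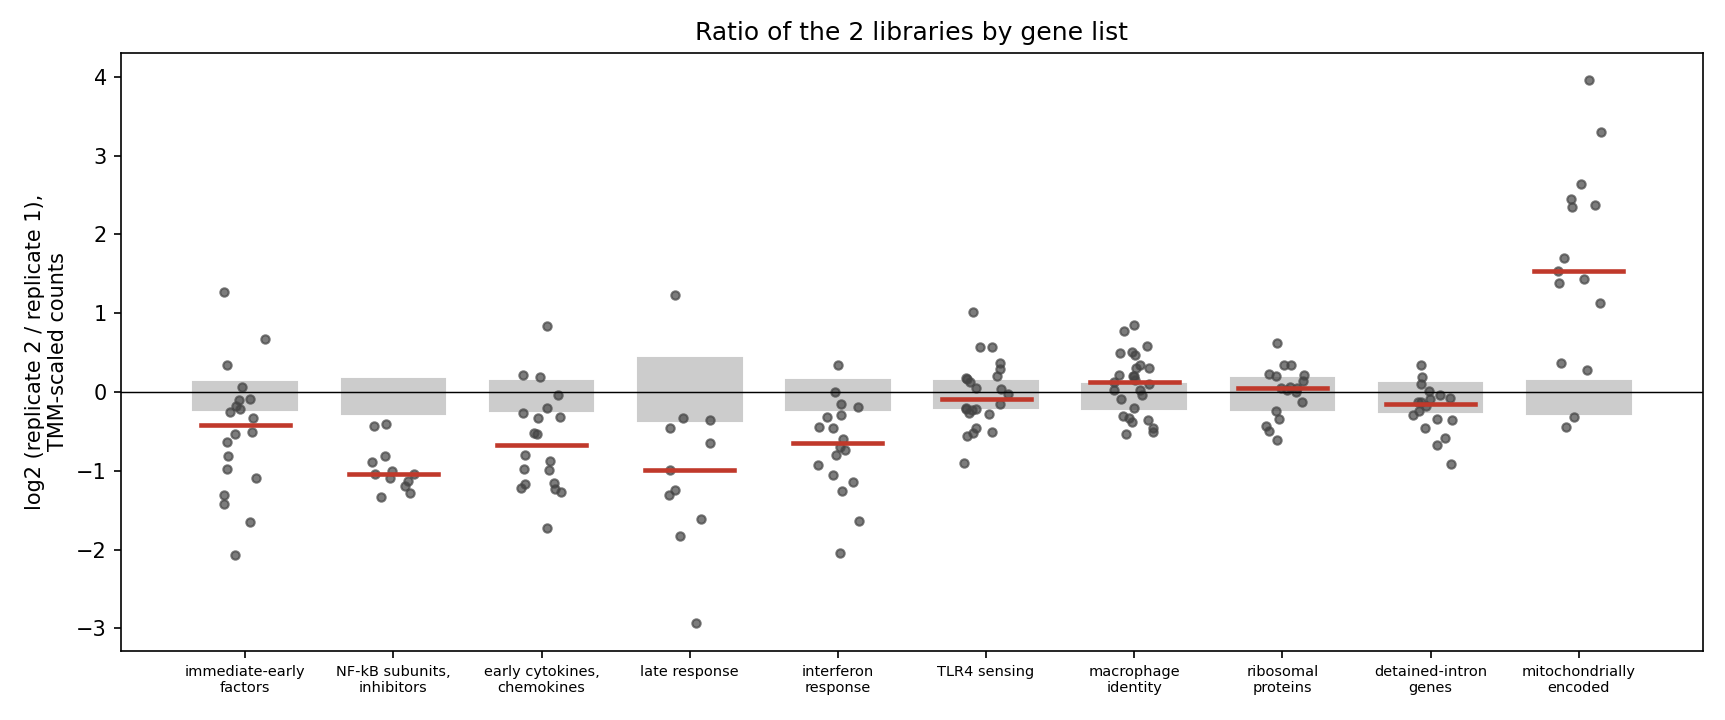
Points are log2 ratios of replicate 2 over replicate 1 for list members, red bars are list medians, and grey boxes are the central 95% of random matched lists. The NF-kB median lies at -1.04 and the mitochondrial median at 1.53, both outside their boxes, and the TLR4 sensing median lies inside its box at -0.09.

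Each library was quantified by 2 methods at the transcript level, and the gene sums were compared. Spearman's rho across genes at 1 TPM or more in both tables was 0.896 in replicate 1 (12382 genes) and 0.901 in replicate 2 (12862 genes). The median log2 ratio of the second table over the first was -0.95 in replicate 1 and -0.0377 in replicate 2. After centring on it, 1527 genes in replicate 1 and 1377 genes in replicate 2 differed by over 2-fold between the tables. Fos, Tnf and Nfkbia were detected in both tables in both libraries.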

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

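The tests of explanations in this part were chosen after the result was seen, and the medians of the fixed gene lists that they use were planned. The phiX174 control sequence, which no comparison used, held 150987 counts in replicate 1 and 38616 in replicate 2, above the 3 counts that an absent signal allows. The numbered entries held 30 and 94 counts, summed over 26248 entries. That limit does not bound stray alignments, so it does not show a signal in the numbered entries.

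NF-kB, early cytokine and interferon genes were lower in replicate 2, with medians of -1.04, -0.67 and -0.65 on the log2 scale. The ratio fell with GC content over 11743 coding genes, from a median of 0.19 in the lowest of 10 equal bins to -0.31 in the highest, but with this trend taken out the medians were -0.78, -0.66 and -0.66, so GC content alone does not account for them. A lower share of macrophages is argued against by the macrophage identity list, which did not fall with them and had a median of 0.13. Its median was 0.0106 with the GC trend taken out and -0.22 with TPM ratios, where the NF-kB median was -1.33. Scaling moves all lists alike, so only this gap between lists bears on the question, and the macrophage value alone does not. RNA input stays open and cannot be told apart from replicate, because each input has 1 library. A difference in the timing or strength of the response, or one present before lipid A was added, was not tested, since no unstimulated library was used here.

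Mitochondrial RNAs were higher in replicate 2 (median 1.53). Ribosomal protein mRNAs did not rise with them, at a median of 0.0491. This does not decide on cytoplasmic RNA carried over, which stays open. Such mRNAs are also made in the nucleus, and the scaling centres most genes near 0, so a rise shared by most mRNAs would not show. Reads shared with 6 nuclear copies on chromosome 1 (24611535 to 24616197, mm10) are not the whole cause, since mitochondrial and copy counts summed had a log2 ratio of 1.86. The 5 mRNAs outside the copied span shared 0% of their 31-base words with annotated copies. RNA made in mitochondria was therefore present in both libraries, and these mRNAs were higher in replicate 2, by 1.44 to 2.63. Whether it was carried over as whole mitochondria stays open. Their range was 1.20 against 2.2 for as many abundant nuclear genes, but with mt-Nd3 counted as uncopied the range was 2.95 against 2.43. The mt-Nd3 gene, singled out after its values were seen, had a log2 ratio of -0.32 in the first quantification and 1.32 in the second.

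Small nucleolar RNAs were lower in 24 of 30 genes or families of equal counts (median -1.26), and small nuclear RNAs were higher in 10 of 17 (median 0.83). This split by class was made after the ratios were seen and used the first quantification only. The planned list of small structured RNAs, which mixes these classes, was lower in 9 of 11 members (median -1.11, percentile 0). Its median was -0.67 with the second quantification. Length stays open: between 120 and 220 nt the small nuclear and small nucleolar RNA medians differed by 2.29. That window held 26 of 30 small nucleolar and 17 of 17 small nuclear RNA genes or families, and lengths were not matched within it. It therefore hardly tested length. The GC trend of coding genes does not account for the difference, which was 2.14 after that trend was taken out. Bin medians of that trend spanned only 0.19 to -0.31, and a GC effect particular to these short RNAs was not tested. A lower yield of nucleolar RNA in replicate 2 stays open: 8 Cajal-body RNAs, guide RNAs outside the nucleolus, had a median of -0.61, with 5 lower and 1 higher beyond counting error, so by their median they neither stayed level nor fell as far as the snoRNAs. Their summed class went the other way, from 0.109% of counts in replicate 1 to 0.132% in replicate 2. Summed small nucleolar RNAs went from 0.0638% to 0.0397%. No biological explanation was tested for this pattern or the mitochondrial one, since there is 1 group.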

How the results depend on the processing

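Of the alternative values, 462 stayed within the spread or within 1.5 times of a count, 106 moved beyond it and 7, of list medians whose counting interval is clear of 0, changed sign. Another 6 values, of list medians whose counting interval includes 0, also changed sign and are counted with the first 2 groups. Ratios adjusted for GC content or length, list medians from TPM ratios or the second quantification, and counts without mitochondrial genes and pseudogenes were chosen after seeing the data. The causes were not tested except where a setting's construction gives them. With 2 libraries, leaving out 1 moves a mean by less than 1 SD by construction, so it tests no mean. It moved the percentile of the detained-intron list, which lay between 77.5 and 97.8. No paired analysis was possible because there is 1 group.

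Rescaling TPM over long nuclear genes raised every level by construction, to medians of 476 (immediate-early), 90.8 (NF-kB), 380 (early cytokine), 1.86 (late), 85.1 (interferon) and 638 TPM (macrophage), and gave 11 detected late genes. The second quantification gave medians of 82.2 (immediate-early), 78.5 (early cytokine), 16.6 (interferon) and 109.8 TPM (macrophage), and 8 detected late genes. Detected late genes numbered 16 at a minimum of 0.1 TPM and 1 at 5 TPM. Posterior-mean TPM gave medians of 0.86 (late) and 196 TPM (macrophage), and the macrophage median was 235 in FPKM.

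The early against late difference was 4.06 with a pseudocount of 1, 4.02 over members at 0.1 TPM or more, 3.97 with the second quantification and 4.55 with CPM. As shares of TPM, protein-coding genes took 33.9%, long intergenic noncoding RNAs 4.98% and misc_RNA 22.2%. With the second quantification these shares of counts were 73.3%, 12.5% and 2.46%, and without mitochondrial genes and ribosomal RNA loci the protein-coding share was 75.3%.

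Genes over 2-fold higher in replicate 2 and in replicate 1 numbered 319 and 1707 with TPM ratios, 146 and 194 at a minimum of 100 (fewer genes tested), and 1852 and 1043 with the second quantification. With library totals the split was 529 and 746. With library totals the list medians were -0.51 (immediate-early), -1.14 (NF-kB), -0.75 (interferon) and 0.0302 (macrophage). With TPM ratios, where all genes had a median of -0.36, they were -0.76, -1.33, -0.99 and -0.22, and -1.01 for early cytokines. With GC content adjusted they were -0.29 (immediate-early), -0.78 (NF-kB) and 0.0106 (macrophage, percentile 92.1). The second quantification gave -0.52, -1.14 and 0.0668 for those 3 lists.

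Nuclear noncoding RNAs changed sign to -0.0726 (GC adjusted), -0.46 (TPM ratios) and -0.0359 (second quantification), dendritic markers to -0.28 (second quantification), proliferation genes to -0.0413 and housekeeping genes to -0.21 with TPM ratios. The detained-intron share was 55.5% of counts, at percentile 99.97. Spearman's rho between the quantifications was 0.893 at a minimum of 0.1 TPM and 0.882 at 5 TPM. Depth limits genes near 0.165 CPM in replicate 1 and 0.161 CPM in replicate 2, the levels that a count of 0 allows.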

Other observations

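Detained-intron genes, which include SR protein and CLK kinase genes, were abundant in the nucleoplasm, with a median TPM of 150 ± 24.0 (SD, n = 2), led by Rsrp1 at 539 ± 246 TPM and Ddx5 at 538 ± 76.5 TPM. Ribosomal protein genes had a median of 37.6 ± 6.51 TPM (SD, n = 2). Noncoding snoRNA host genes had a median of 11.1 ± 3.51 TPM, led by Gas5 at 73.3 ± 13.2 TPM (SD, n = 2). Housekeeping genes had a median of 41.6 ± 1.21 TPM, with Actb at 926 ± 205 TPM (SD, n = 2).

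The longest annotated transcript of Neat1 had 306998 counts in replicate 1 and 171640 in replicate 2, and the annotated transcript Neat1-202 had 77480 and 55744. In TPM the order was the opposite, with 786 and 360 for the longest transcript and 1458 and 858 for Neat1-202.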
